A study of Mus musculus with 4 samples.

How the data were processed

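Poly(A)-selected RNA from granulocyte-monocyte progenitors, the bone marrow cells that give rise to neutrophils and monocytes, was sequenced from wild-type and MST1-deficient mice. Each group held 2 libraries, and each library came from cells pooled from 10 mice, per the labels. RNA was taken up on oligo-dT beads, copied to cDNA and amplified by PCR, per the labels' protocols. The sorted cells were held in serum-containing culture medium and received no drug, per the labels' protocols. The series lists no batch, date, sex or age of the mice.

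The files used here held, for each library, a list of transcripts and a list of genes whose identifiers mark them as lying outside the reference annotation. Such transcripts are called unannotated transcripts below. Most belonged to a known gene, given by its NCBI gene number, and the others to a locus with no such number, called an unannotated gene below. Values for the annotated transcripts of the same genes were not analysed here, so a value given for a gene covers its unannotated transcripts alone. Each list held values above 0 in its own library, and a transcript missing from a list was set to 0 there when another library listed it. The genome build was mm10, per the submitters' processing notes. The aligner, the transcript assembler, the estimator and the annotation were not given in the sources used here.

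The authors deposited estimated counts (expected counts) per transcript, which were not normalised and mostly not whole numbers. They also deposited FPKM, that is, estimated counts scaled to transcript length and library size, per the file headers. The ratio of FPKM to estimated count and length gave implied library totals of 7982080 and 7406767 for wild type and 6913648 and 8518504 for MST1-deficient replicates 1 and 2. The listed transcripts summed to 1079382 and 947305 estimated counts in wild type and to 928977 and 1002807 in MST1-deficient replicates 1 and 2. PCR copies were not marked by molecular identifiers, so any interval or floor covers counting error only. Gene numbers were matched to symbols and positions through a RefSeq table of GRCm38.p6, the same build as mm10. Of 5059 annotated genes in any library, 5051 matched and 8 did not.

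The groups were compared with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, 2-sided) on estimated counts rounded to whole numbers, under R 4.3.3. The design called for this test if the files held counts, and for limma on FPKM otherwise. Features needed an FPKM of at least 1 in at least 2 of the 4 libraries. P-values were adjusted by the Benjamini-Hochberg method over the features tested, with a threshold of 0.05. The test was run on transcripts, on unannotated genes, and on the sum of all unannotated transcripts of each annotated gene. The balance among the transcripts of a gene was tested with diffSplice of limma 3.58.1 on log2(FPKM + 0.5), with Simes-adjusted p-values per gene. Gene lists were tested with camera on the same scale for the gene sums, with a preset correlation of 0.01 and at least 3 tested members. Beside it stand camera with an estimated correlation and fry.

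The tests, the alternatives, 29 gene lists and the rule for naming genes were fixed before the data were examined. That rule took the 15 higher and 15 lower features with the largest fold change among those past the threshold with no overlap between the groups. Where fewer than 5 passed in a direction, it took the 10 with the smallest p among features without overlap, given as values that did not pass. It added the gene of MST1, list members past the threshold (up to 6 a list) and the 5 genes with the smallest p for the balance of transcripts. Some items that this rule names are not reported here. A fold against a group at 0 was computed against a floor of 3 counts per library and is a lower bound. Fold changes on the log2(FPKM + 0.5) scale understate changes of low values.

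The alternatives were limma on log2(FPKM + 0.5), other pseudocounts (0.1 and 1), median centring, quantile normalisation, DESeq2 1.42.0, another size factor (RLE), robust moderation, other filters, the replicate number as a block, and each library left out. For single features, the p-values of edgeR, DESeq2 and limma measure the spread between 2 pools per group. Whether the pools of a group were prepared on separate days is not given. The diffSplice test pools the spread over all transcripts of a gene and treats them as independent. Camera with the preset correlation rests mainly on the spread among genes. Neither of these p-values measures the spread between pools alone. An exact permutation test of 2 against 2 has 3 splits and cannot go below 0.33, so single values such as transcripts per library were not tested.

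The tests were checked on simulated data drawn from the real means, library sizes and fitted dispersions. For transcripts (4661 features), edgeR recovered 2% of the 4-fold and 30% of the 16-fold changes. For gene sums (3221 features) it recovered 26% of the 4-fold and 75% of the 16-fold changes, with 8 false calls, and made 5 calls when nothing was changed. For unannotated genes (185 features) it recovered 0 of 10 changes of 4-fold and 6 of 10 of 16-fold. The test of transcript balance recovered 35 of 50 genes with 1 transcript shifted by 4 on the log2 scale, with 2 false calls among 909 genes. This noise did not model transcripts that drop to 0 in a library, so the check does not measure false calls from such transcripts. In a simulation of 25 lists, camera gave the 1 shifted list an adjusted p of 5.17e-10 and called 1 other list. Genes were drawn independently of each other there, so this cannot test the preset correlation.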

Results

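Granulocyte-monocyte progenitors from the bone marrow of wild-type and MST1-deficient mice were compared by RNA-seq, with 2 libraries of 10 pooled mice in each group. MST1 was taken to be the serine/threonine kinase of the Hippo pathway that Stk4 encodes in the mouse; the labels do not name the gene. The values describe transcripts outside the reference annotation, with 6774 and 6528 listed in wild-type replicates 1 and 2 and 6745 and 6517 in MST1-deficient replicates 1 and 2. These belonged to between 4311 and 4438 annotated genes per library and to between 195 and 233 unannotated genes. Total estimated counts ranged from 928977 to 1079382 per library.

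The kinase gene itself could not be checked. No unannotated transcript of Stk4 (chromosome 2, 164074113 to 164155524), of its close relative Stk3, or of the unrelated macrophage stimulating gene Mst1 was listed in any of the 4 libraries. Annotated transcripts of these genes were not analysed here, so the labels alone define the groups.

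Many unannotated transcripts appeared in some libraries and were absent from others. Of 8219 transcripts listed in any library, 4974 were listed in all 4 and 1056 in 1. Both wild-type libraries and neither MST1-deficient library listed 162 transcripts, and 183 showed the opposite pattern. The pairings that do not follow genotype also gave such transcripts. Both libraries numbered 1 and neither numbered 2 listed 214, and both numbered 2 alone listed 109.

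Across the summed unannotated transcripts of each gene, the genes with the smallest p-values were Cep85, which encodes a centrosomal protein, and Myl12a, which encodes a regulatory light chain of non-muscle myosin. Cep85 (gene 70012, chromosome 4, 134129858 to 134187085) had 401 ± 81.4 FPKM (SD, n = 2) in MST1-deficient and 2.17 ± 1.51 in wild-type libraries, a log2 fold change of 7.58 with an SE of 0.48. Myl12a (gene 67268, chromosome 17, 70993793 to 71002533) had 934 and 690 estimated counts in the MST1-deficient libraries and 0 in both wild-type ones, at least 281-fold higher. The gene of the aspartic protease cathepsin E, Ctse, had 221 ± 14 FPKM against 46.4 ± 9.96, a log2 fold change of 2.32 with an SE of 0.21. Klhl12, an adaptor of a cullin ubiquitin ligase, had 194 and 203 counts in wild type and 0 in both MST1-deficient libraries, at least 63.9-fold lower.

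None of these differences passed the edgeR threshold: 0 of 3221 genes did, and the lowest adjusted p was 0.112. At an unadjusted p under 0.05 there were 182 genes, 97 higher and 85 lower in MST1-deficient cells. The split of the libraries by replicate number gave 201 such genes, the remaining split gave 64, and simulated data without any change gave 163. DESeq2 called 46 genes (22 higher, 24 lower), and limma on FPKM called 6. The 6 limma calls were Cep85, Myl12a, Ctse and Chd9, all higher, and Btbd9 and Tmed5, both lower. All 20 genes named from this comparison were among the DESeq2 calls, and none passed with edgeR.

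Among the other genes with higher values, Chd9, a chromodomain helicase (chromosome 8), had a log2 fold change of 2.07 with an SE of 0.20 on counts (4.2-fold), and 241.4 ± 34.7 FPKM (SD, n = 2) against 26.36 ± 8.224. Camk2b, a subunit of a calcium- and calmodulin-dependent kinase, had 357 ± 109 FPKM (SD, n = 2) against 93.3 ± 25.5. Mllt10, a partner gene of leukaemia fusions, had 6.17 ± 1.27 FPKM against 1.40 ± 0.0212. Galnt11, a glycosyltransferase that starts O-linked sugar chains, had 29.6 ± 6.63 against 5.13 ± 1.45. Cc2d1a was listed at 0 in both wild-type libraries and had 85.6 and 159 counts in the MST1-deficient ones, at least 42.4-fold higher. Gm14440 and gene 100190996 had log2 fold changes of 1.54 (SE 0.23) and 1.93 (SE 0.25). Gm14440 belongs to a family of similar zinc finger genes and Myl12a has a near-identical neighbour, Myl12b, so the split of reads between such copies is uncertain.

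Among genes with lower values, 5 of the 10 named were at 0 in both MST1-deficient libraries. Besides Klhl12 these were Gcn1, a sensor of stalled ribosomes in the amino acid response (at least 94.6-fold lower), and Rasgrp1, a Ras activator in lymphocytes (at least 80.0-fold). The other such genes were Btbd9 (at least 48.9-fold) and Tmed5, a cargo receptor of the early secretory pathway (at least 28.8-fold). Dnah8, an axonemal dynein heavy chain, had 12.96 ± 0.438 FPKM (SD, n = 2) in wild type and 3.11 ± 0.177 in MST1-deficient cells. Col5a1, a fibrillar collagen gene, had 11.2 ± 0.191 against 2.50 ± 0.0990. Klrc1, an inhibitory receptor of natural killer cells with close relatives in the same cluster, had 21 ± 1.82 against 4.16 ± 0.255. Rnf40, a ligase for histone H2B, had 9.84 ± 1.15 against 2.53 ± 0.0283, and Armc6 had 7.29 ± 1.87 against 0.110 ± 0.0849 (25.4-fold lower on counts). FPKM weighs short transcripts more than counts do, so the scales can differ for a gene sum.

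**Figure D1:**
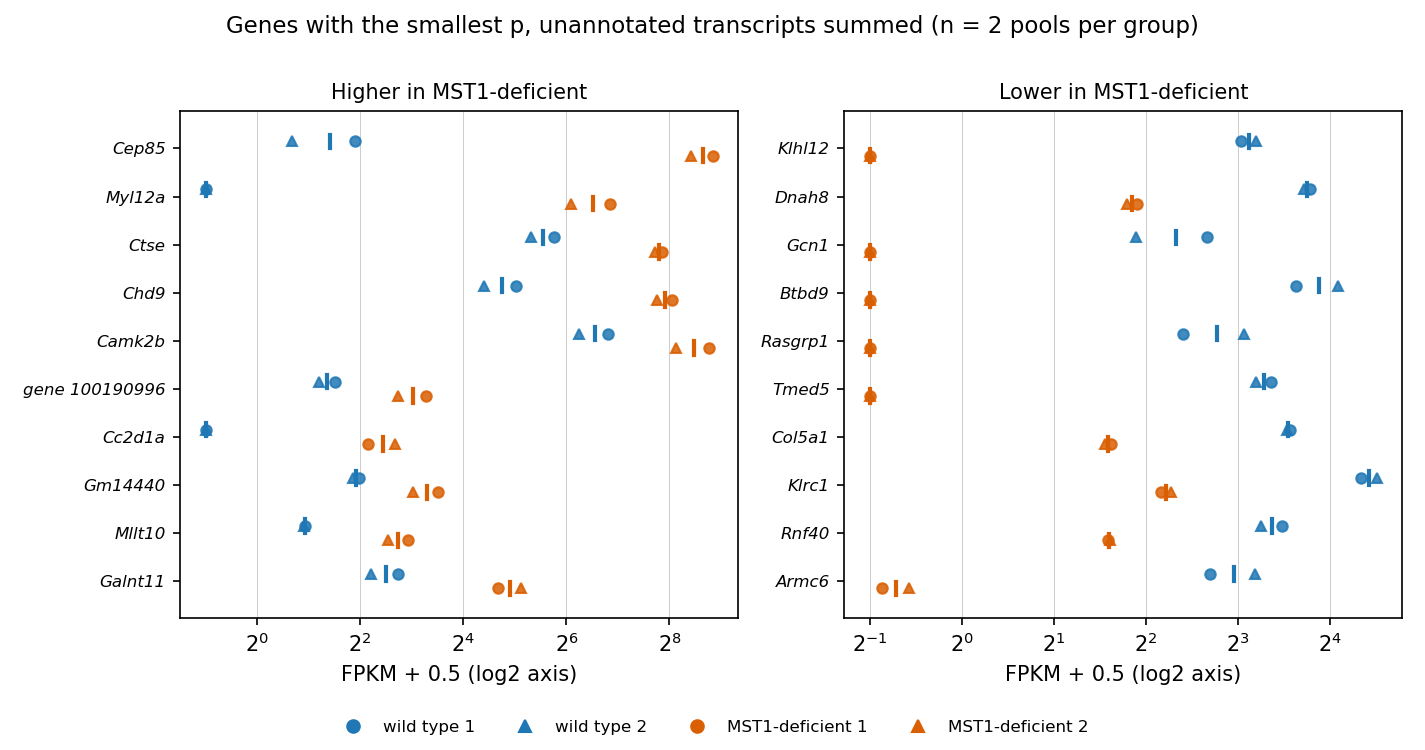
Each point is 1 library (2 pools per group, circles replicate 1, triangles replicate 2), plotted as FPKM + 0.5 on a log2 axis for the 10 genes with the smallest p in each direction among genes whose groups do not overlap, and each bar marks the group mean. Cep85 lies near 401 FPKM in MST1-deficient and 2.17 in wild-type libraries, and the 7 genes with 1 group at 0 sit at the left edge for that group.

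Genes of the Y chromosome also differed between the libraries. Kdm5d, Uty, Ddx3y and Eif2s3y were at 0 in wild-type replicate 2 and lower in wild-type replicate 1 than in both MST1-deficient libraries. Ddx3y, an RNA helicase gene, had 1.91 and 0 FPKM in wild type and 10.2 and 5.60 in MST1-deficient libraries. Kdm5d, a histone demethylase gene, had 0.02 and 0 FPKM against 2.59 and 3.19. None of the 4 passed the edgeR threshold, with adjusted p between 0.351 and 0.943. The sex of the mice is not given, so a difference in sex between the pools could enter any comparison of the groups.

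At the level of single transcripts, contrasts lay in Tuba1a, an alpha-tubulin gene, and in genes with transcripts listed in 1 group alone. A transcript of Tuba1a had 4108 and 4807 counts in wild type and 725 and 755 in MST1-deficient cells, with a log2 fold change of -2.55 and an SE of 0.27. A transcript of the cation channel gene Trpm2 and a transcript of Erdr1 were listed in the MST1-deficient libraries alone, at least 42.4-fold and 51.1-fold higher. A transcript of the deubiquitinase gene Usp9x and a transcript of the histone methyltransferase gene Kmt2c were listed in wild type alone, at least 79.1-fold and 55.6-fold lower. The summed unannotated transcripts of Kmt2c differed little, with 5.295 ± 0.9122 FPKM (SD, n = 2) in wild type and 5.78 ± 1.259 in MST1-deficient libraries. A transcript of Herc1, a very large ubiquitin ligase, had 168 and 249 counts in the MST1-deficient libraries against 0 and 0.92.

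Of 4661 transcripts tested, 0 passed with edgeR, where the lowest adjusted p was 0.0695. There were 245 at an unadjusted p under 0.05, 106 higher and 139 lower, against 270 for the split by replicate number, 117 for the remaining split and 233 in simulated data without any change. DESeq2 called 100 transcripts (50 higher, 50 lower), and limma on FPKM called 6 (5 higher, 1 lower). Tuba1a has near-identical relatives elsewhere in the genome, so the assignment of reads to its transcripts is uncertain.

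The balance among unannotated transcripts changed in 11 of 909 genes with at least 2 tested transcripts. With the replicate number as a block the count was 0 (lowest adjusted p 0.0857), and it was 0 without wild-type replicate 1 and without wild-type replicate 2. In Asxl1, a chromatin regulator mutated in myeloid disease, a transcript of 6994 bases made up 28.3 ± 14.2% (SD, n = 2) of the FPKM in wild type and was listed at 0 in MST1-deficient cells. A transcript of 6965 bases was at 0 in wild type and made up 32.3 ± 8.3% in MST1-deficient cells, while another form of 6479 bases made up 71.7 ± 14.2% and 67.7 ± 8.3% (adjusted p of the gene 0.0061 with diffSplice).

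In Cast, which encodes the calpain inhibitor calpastatin, a transcript of 8363 bases was at 0 in wild type and made up 24.2 ± 19.3% (SD, n = 2) in MST1-deficient cells (adjusted p = 0.017 with diffSplice). In Plekha1, a phosphoinositide-binding adaptor, a form of 3665 bases made up 41.9 ± 24.2% in wild type and was at 0 in MST1-deficient cells (adjusted p = 0.0197). In gene 18729, whose number matched no symbol, a form of 2071 bases made up 77.5 ± 0.7% and 21.8 ± 0.0% (adjusted p = 0.017). The summed level of Asxl1 differed little, with 18.5 ± 0.127 FPKM in wild type and 15.4 ± 2.001 in MST1-deficient cells.

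There were 88 genes at an unadjusted p under 0.05. The number of changed genes was 3 without MST1-deficient replicate 1 and 7 without MST1-deficient replicate 2. It was 25 with a pseudocount of 0.1 and 1 among transcripts above 0 in all 4 libraries.

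**Figure D2:**
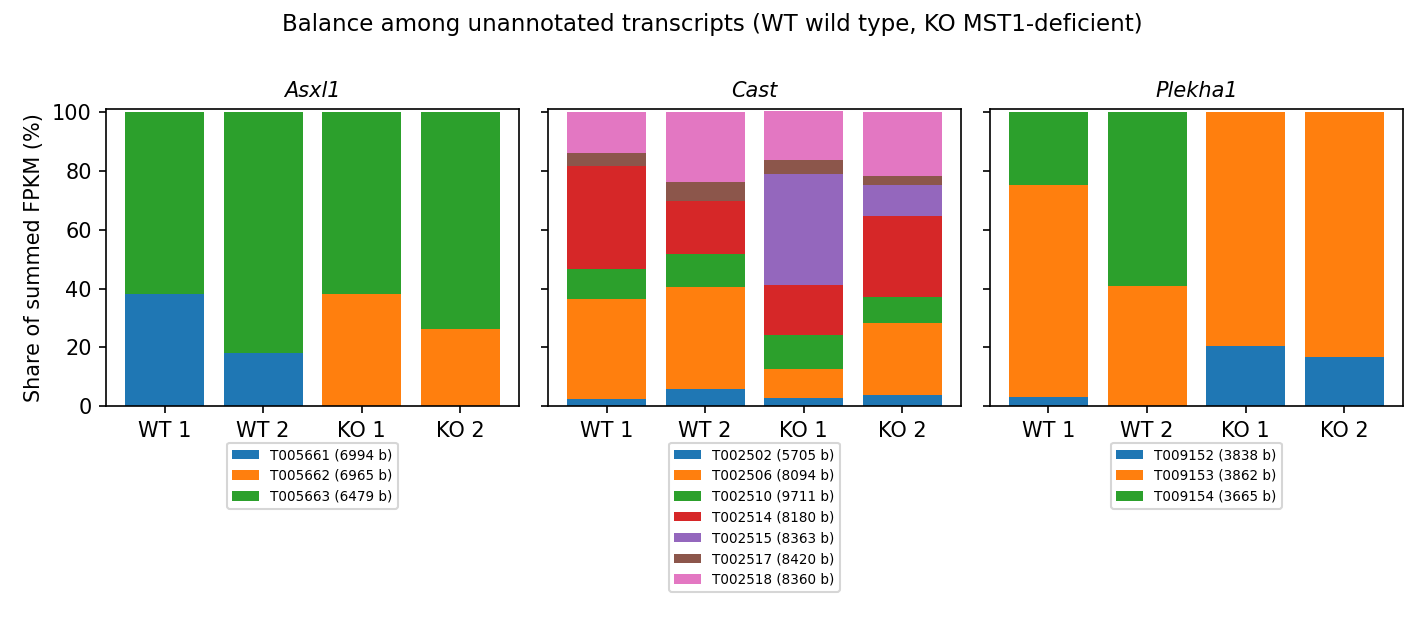
Stacked bars give, for each library (WT wild type, KO MST1-deficient, replicates 1 and 2), the percentage of the summed FPKM of a gene's tested unannotated transcripts held by each transcript, named by its number and its length in bases. In Asxl1 the form of 6994 bases and in Plekha1 the form of 3665 bases are at 0 in both MST1-deficient libraries, and in Cast the form of 8363 bases is at 0 in both wild-type libraries.

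Among 185 unannotated genes tested, 1 fell in MST1-deficient cells. This locus, novel_G000311 with 1 transcript of 1118 bases, had 7579 and 8197 estimated counts in wild type and 2 and 1.02 in the MST1-deficient libraries. The ratio of summed counts, scaled by TMM-adjusted library sizes, was 4720-fold with an exact 95% interval of 1610 to 22900 for counting error alone (edgeR log2 fold change -12.06, fitted separately, SE 0.61, adjusted p 0.00588). With the replicate number as a block the fold and SE stayed near those values but the call was lost (log2 fold change -12.098, SE 0.669, adjusted p 0.137). The block leaves fewer degrees of freedom for the error, and how far this alone raised the edgeR p-value was not tested. Among the 4661 transcripts the same counts did not pass (log2 fold change -12.202, SE 0.473, adjusted p 0.0695). The call was also lost without wild-type replicate 1 (log2 fold change -12.026, adjusted p 0.117) and without wild-type replicate 2 (-11.836, 0.12). It was kept without MST1-deficient replicate 1 (-12.782, 0.000372) and without MST1-deficient replicate 2 (-11.53, 0.000661). Its FPKM was 1047 ± 110 (SD, n = 2) in wild type, which placed it among the abundant unannotated genes. Its position in the genome was not given in the sources used here. Of 40 unannotated genes with at least 500 counts in a library, 8 were below 10% of their highest library in MST1-deficient replicate 1 alone. There was 1 such gene in MST1-deficient replicate 2 alone, and this locus was the 1 below 10% in both. Separate losses in the 2 libraries were not told apart from an effect of genotype.

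At an unadjusted p under 0.05 there were 24 unannotated genes, 2 higher and 22 lower in MST1-deficient cells. Of the 24, 17 belonged to 2 runs of consecutively numbered short genes that were picked after the results were seen. MST1-deficient replicate 1 stood apart at this level, with 11.8% of its estimated counts in unannotated genes and a TMM factor of 1.184. The other libraries had 15.7% to 18.5% and factors of 0.937 to 0.95. A locus of 2133 bases, novel_G000353, was at 0 in wild type and had 15.4 and 33.1 counts in the MST1-deficient libraries, at least 8.74-fold higher. A locus of 1996 bases, novel_G000320, had 38.6 ± 4.12 FPKM (SD, n = 2) against 8.29 ± 2.88. The median log2 fold change over the 185 genes was -0.43 and depended on scaling: it was -0.49 for limma on FPKM, -0.19 with RLE size factors and -0.58 with the implied library totals. Median centring gave 0.72, with 40 genes higher and 9 lower at an unadjusted p under 0.05, and quantile normalisation gave 0.34, with 20 higher and 10 lower. The number that passed was 4 without MST1-deficient replicate 1 and 17 without MST1-deficient replicate 2, and DESeq2 called 4.

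With camera at the preset correlation, the interferon response genes were higher as a list in MST1-deficient cells and the genes of eosinophils, basophils and mast cells were lower (adjusted p = 0.0193 for both). Both calls were lost with an estimated correlation (adjusted p = 0.996) and with fry (adjusted p = 0.933). Camera also lost both with no filter (adjusted p = 0.278) and among genes above 0 in all 4 libraries (0.0952 for interferon, 0.126 for the other list). Median centring lost the eosinophil, basophil and mast cell list (0.107) but kept the interferon list (0.0307). Both were kept with other pseudocounts, quantile normalisation and the replicate block. Of 10 tested interferon response genes, 9 had a positive difference, and 5 had both MST1-deficient libraries above both wild-type ones, where chance gives 16.7% in 1 direction. Oasl2, an interferon-induced oligoadenylate synthetase-like gene, had 3.39 ± 1.16 FPKM (SD, n = 2) against 1.09 ± 0.0424. Trim30a had 12.4 ± 0.990 against 9.33 ± 0.198, and Zbp1, a sensor of nucleic acids, had 2.96 ± 0.163 against 1.66 ± 0.276. The exception was Xaf1, with 38.0 and 56.8 FPKM in wild type and 0 and 45.0 in the MST1-deficient libraries.

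All 4 tested genes of the eosinophil, basophil and mast cell list had both MST1-deficient libraries below both wild-type ones. Prg3, an eosinophil granule protein gene, had 4.42 ± 0.375 FPKM (SD, n = 2) against 8.04 ± 2.04, and Ms4a2, the beta chain of the high-affinity IgE receptor, had 25.6 ± 6.93 against 43.6 ± 8.82. Alox15, a lipoxygenase gene, had 26.0 ± 3.73 against 42.7 ± 13.4, and Gata2, a transcription factor of progenitors and mast cells, had 63.7 ± 0.962 against 76.5 ± 3.29.

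No member of either list passed the edgeR threshold over all genes or adjusted over the list alone. The interferon call was absent without wild-type replicate 1 (adjusted p = 0.503), MST1-deficient replicate 1 (0.128) or MST1-deficient replicate 2 (0.488), and the other call without wild-type replicate 2 (0.451), MST1-deficient replicate 1 (0.300) or MST1-deficient replicate 2 (0.0524).

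**Figure D3:**
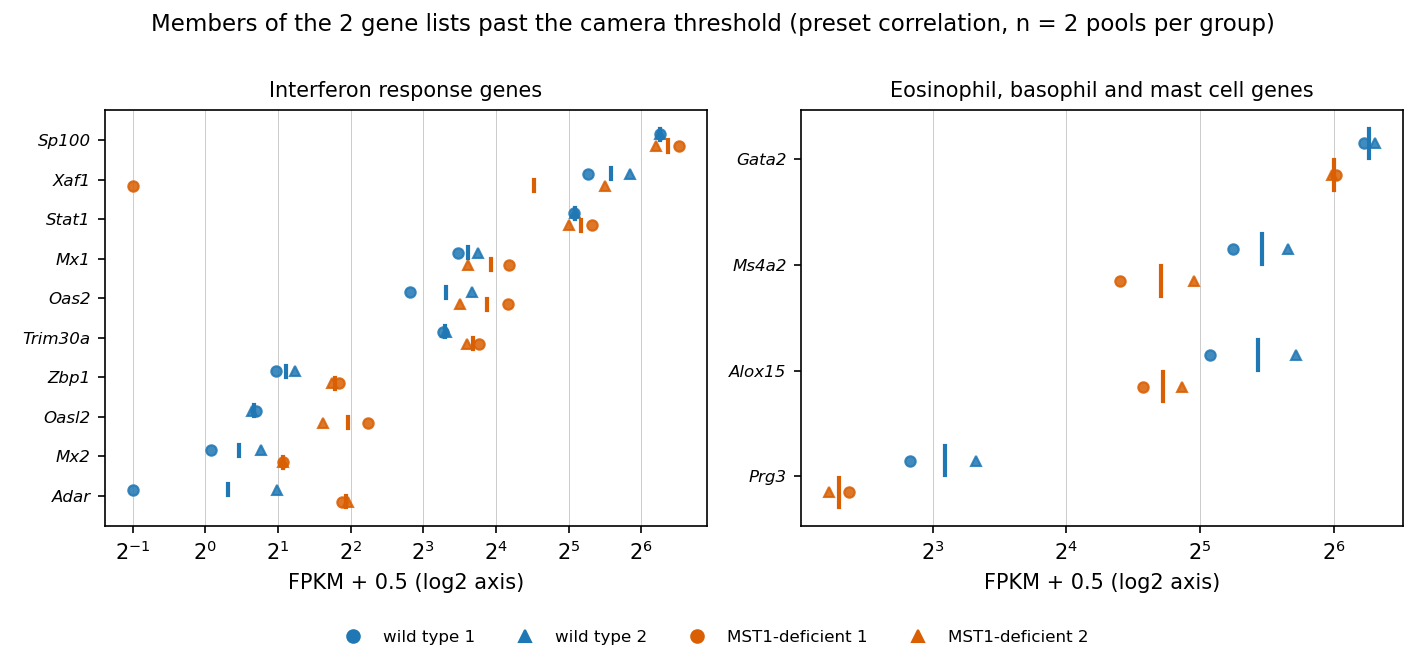
Each point is 1 library (2 pools per group, circles replicate 1, triangles replicate 2), plotted as FPKM + 0.5 on a log2 axis for the tested members of the 2 lists, and each bar marks the group mean. In the eosinophil, basophil and mast cell list 4 of 4 genes have both MST1-deficient libraries below both wild-type libraries, and in the interferon list Xaf1 is at 0 in 1 MST1-deficient library.

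The other 23 lists did not pass, with a lowest adjusted p of 0.244 for the erythroid genes (camera). Which list ranked first depended on the libraries. It was the B lineage genes, higher, without wild-type replicate 1 and the erythroid genes, lower, without MST1-deficient replicate 1. Without either of the other libraries it was a list called in the main test. All 5 tested erythroid genes had negative differences on the FPKM scale. Sptb, the erythroid spectrin beta chain gene, had 5.40 ± 3.52 FPKM (SD, n = 2) against 14.8 ± 1.37, and Ank1, the erythroid ankyrin gene, had 3.61 ± 2.95 against 7.91 ± 3.65. Tal1, a transcription factor of the lineage, had 4.14 ± 1.04 against 4.32 ± 0.219. None of the 8 tested Hippo pathway genes had an unadjusted p under 0.05. Sav1, the scaffold partner of MST1, had 1.51 ± 0.778 FPKM against 1.23 ± 0.368, and Mob1b, a substrate of the kinase, had 3.46 ± 0.134 against 3.62 ± 0.332. Camera compares the test statistics of a list with those of the other genes, not median differences. For the Hippo, monocyte, ribosomal protein, apoptosis, glycolysis, adhesion, and T and NK cell lists its direction was up although their median differences were below 0.

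Genes of the progenitors and their neutrophil and monocyte descendants gave 0 edgeR calls. Of 6 tested genes of myeloid progenitors, 5 had positive differences, and Gfi1, a transcription factor of granulocyte fate, had 33.3 ± 18.9 FPKM (SD, n = 2) against 22.8 ± 8.80. The receptor gene Csf3r had 54.8 ± 4.72 against 49.7 ± 26.3. Of 8 tested genes of later neutrophils, 1 had an unadjusted p under 0.05: Ncf4, a subunit of the phagocyte oxidase, was at 0 in both MST1-deficient libraries and had 1.17 and 1.62 FPKM in wild type. The receptor gene Cxcr2 had 14.4 ± 12.8 against 36.0 ± 20.1. The macrophage gene Mpeg1 had 188 ± 65.1 against 172 ± 65.0.

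Vpreb3, a component of early B cell receptors, differed between the wild-type libraries, with 29.0 and 2.58 FPKM in wild-type replicates 1 and 2 and 9.54 and 8.85 in the MST1-deficient libraries. Across all lists, 195 genes were tested, 9 had an unadjusted p under 0.05, 0 passed edgeR over all genes, and 1 passed adjusted over the list alone. That gene was Hk3, a hexokinase gene, which was at 0 in wild type and had 1.53 and 3.29 FPKM in the MST1-deficient libraries (adjusted p 0.0271 over the glycolysis list with edgeR).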

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

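The fits on implied library totals and the fit without the 2 runs of short genes were chosen only after the results were seen. All counts below are features past an adjusted p of 0.05, and the cause of a shift was not tested unless stated. For transcripts, edgeR gave 0, limma 6, limma with a pseudocount of 0.1 gave 4 and of 1 gave 6, median centring 7, quantile normalisation 6, DESeq2 100, and transcripts above 0 in all 4 libraries 2. For gene sums the values were 0, 6, 2, 7, 4, 2, 46 and 1 in the same order. Robust moderation, RLE size factors, no filter, implied totals and each library left out gave 0 for both. For unannotated genes the count was 1, DESeq2 gave 4, and leaving out a library gave between 0 and 17; the other settings gave 1, also without the runs, apart from the replicate block below. A lone library left in a group is assumed to vary like the other group.

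For the balance of transcripts the count was 11, with 25 at a pseudocount of 0.1 and 7 at 1, 7 with no filter, 1 above 0 in all 4 libraries, 15 with median centring, 13 with quantile normalisation, and between 0 and 7 with a library left out. For gene lists the count was 2, with 0 for no filter, 0 above 0 in all 4 libraries, 1 with median centring, 0 with an estimated correlation, 0 with fry, and between 0 and 3 with a library left out. The locus novel_G000332, with a log2 fold change of 0.04, reversed to -0.142 with limma at each pseudocount, -0.084 with quantile normalisation and -0.123 with implied totals, rose to 1.067 with median centring and 0.263 with RLE and DESeq2, and ranged from -0.034 to 0.193 with a library left out (-0.034 without MST1-deficient replicate 1). No other named feature changed sign. At an FPKM of at least 1, the listed transcripts were 4437 and 4139 in wild type and 4393 and 3932 in MST1-deficient replicates 1 and 2.

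The labels give both groups the replicate numbers 1 and 2 but no shared day or litter, so whether the numbers pair the samples is unknown. At an unadjusted p under 0.05 (edgeR), the split by replicate number gave 270 transcripts and 201 gene sums, against 245 and 182 for genotype. For unannotated genes it gave 7 against 24. An effect tied to the replicate numbers stays open. With the replicate number as a block, the count was 0 for transcripts, 0 for gene sums, 0 for unannotated genes, 0 for the balance of transcripts and 2 for gene lists. Deviations of equally numbered libraries correlated at 0.126 over transcripts and 0.127 over gene sums. Estimated counts per transcript had a median between 42.9 and 49.8 per library, which limits the precision of most single values.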

Other observations

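The tests of Y-linked genes, B lineage genes, depth and other pairings of the libraries were chosen only after the results were seen. Those of plasma cell genes, immunoglobulin segments, whole counts and the region around Stk4 were written before their own values were computed. The plasma cell and immunoglobulin tests concern runs of short unannotated genes that were picked after the results were seen. Those tests were therefore not fixed before the results.

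Single members of several other gene lists were measured without a call. Rps18, a small-subunit ribosomal protein gene, had 1057 ± 314 FPKM (SD, n = 2) in MST1-deficient and 1857 ± 332 in wild-type libraries, while Rps26 had 3403 ± 393 and 3421 ± 96.2. E2f1, a regulator of entry into S phase, had 4.62 ± 1.12 against 2.37 ± 0.318, and the proliferation marker Mki67 had 42.9 ± 5.47 against 53.0 ± 15.1. Ncr1, a natural killer cell receptor gene, had 8.74 ± 1.58 against 5.17 ± 0.339. The splicing kinase gene Clk1 had 19.8 ± 1.09 against 10.9 ± 2.66. None of these passed the edgeR threshold.

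Most genes in 2 runs of consecutively numbered short unannotated genes had lower values in MST1-deficient cells, and none passed the threshold. Fold changes were negative in 29 of 31 and 16 of 18 tested, against 70 of 136 tested outside the runs. The runs were picked after the results were seen, so these counts are a description and no test. Since 7865 of 7901 neighbouring annotated transcripts are numbered in order of gene start, the 37 genes of 1 run may lie between Mad2l1 and Smyd1 on chromosome 6 (66541107 to 71213940) and the 21 of the other between Pacs2 and Zfp386 on chromosome 12 (113074401 to 116047714). Of the annotated genes of GENCODE M21 between those flanks, 75.7% are immunoglobulin segments, so transcripts of rearranged or unrearranged immunoglobulin genes are a candidate source. On chromosome 6, summed FPKM was 251, 494, 66.9 and 32.8 in wild-type replicates 1 and 2 and MST1-deficient replicates 1 and 2. On chromosome 12 it was 151, 247, 46.4 and 38.7 in the same order, a ratio of 6.20 over both runs. FPKM is already scaled to library size, and the implied library totals, 6913648 to 8518504, cannot give that ratio. Cells of the B lineage or plasma cells could bring such RNA past the sort, and these tests left that open: summed FPKM of 4 B lineage genes was 51.3, 4.30, 19.0 and 17.3, so that wild-type replicate 2 was 0.237 of the MST1-deficient mean. The 4 tested plasma cell genes of a list of 33 (Irf4 is also in the dendritic cell list) summed to 34.5, 28.9, 37.4 and 33.3 FPKM, most of it Tnfrsf13b, and did not follow the runs. Their median log2 difference of -0.34 decides nothing, since members went both ways: Ssr4 was at 0 in wild type and had 4.94 and 3.41 FPKM in the MST1-deficient libraries. An effect of genotype on these loci stays open as well, untested beyond the comparison itself.

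Y-linked genes were a further difference that follows the groups, with all 4 genes examined lower in both wild-type libraries than in both MST1-deficient ones. Any listed Y-linked gene with a symbol starting with Gm was left out. FPKM is already scaled to library size, so a difference in depth is largely removed from these values. The mean implied total of wild type was 0.997 of that of the MST1-deficient libraries. The mean wild-type FPKM of the highest Y-linked gene was 12.1% of the MST1-deficient mean. Pools with different shares of male mice are a candidate explanation for these 4 genes, with wild-type replicate 2 possibly all female, but the sex of the mice is not given. A shared male share would give wild-type replicate 1 the same percentage for each gene. The values were 0.7% for Kdm5d (0.39 counts), 14.6% for Uty, 24.2% for Ddx3y and 22.1% for Eif2s3y, which decides nothing. Since the Y-linked values follow the groups, sex and genotype cannot be told apart here. If the pools differed in sex, this holds for every comparison of the groups, not for these 4 genes alone. No unannotated Xist transcript was listed, and annotated ones were not analysed here, so this absence decides nothing about female cells. An effect of genotype on Y-linked genes was not tested apart from sex.

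Transcripts with at least 30 counts in 1 library were at 0 in another, even within a group. Cases were transcripts with at least 30 counts in a library, compared between replicates of 1 group. With counts that are not whole, 9.97% of 8987 cases were at 0 in the other library. With whole counts (within 0.005 of a whole number in all 4 libraries) it was 12.05% of 166 cases (Fisher's exact test, 2-sided, p = 0.361). A count of 0 is itself whole, so transcripts at 0 in a library enter the whole class more easily. A transcript could also enter once per group, so the cases are not independent. Ambiguous assignment of reads among similar transcripts could therefore neither be shown nor excluded. With at least 30 counts in both libraries of 1 pair and 0 in the other pair, the genotype split gave 69 transcripts, the replicate numbers 61 and the crossed pairing 44. The genotype split was the 1 of 3 splits with the most, and 3 splits are too few for a share under 0.05. A change in transcript use with genotype stays open.

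Of 40 unannotated genes with at least 500 counts in a library, 9 were below 10% of their highest library in MST1-deficient replicate 1. There were 2 in MST1-deficient replicate 2, 1 in both (novel_G000311), and 0 in a wild-type library. Of 69 genes within 20 Mb of Stk4 on chromosome 2, 7.25% had an unadjusted p under 0.05, against 5.62% of 3152 genes elsewhere (Fisher's exact test, 2-sided, p = 0.592).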
